A study of Mus musculus with 8 samples.

How the data were processed

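Poly(A) RNA of ILC2 sorted from mouse thymus was measured in 4 Il25 KO and 4 WT libraries made by MARS-seq, a method that sequences the 3′ ends of transcripts and tags each molecule with a UMI, per the labels' protocols. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq, DESeq2 and the genome build mm10, without giving their roles, settings or the annotation, which are not given in the sources used here. A 3′ count does not depend on transcript length, and reads that match several genes can be lost or split. How such reads, and the strand, were counted is not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain.

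A single deposited table held all values for 10913 genes named by symbol. The raw UMI counts are whole numbers per gene and library, per the file headers, and were the only values used for tests. Every listed gene had at least 6 counts in at least 1 library, a property of the values that no source states as a filter. The normalized signal values, per the file headers, equalled the raw count divided by a constant per library, so they are counts scaled by the authors' size factors. The authors also deposited regularized log2 values and the log2 fold change of WT over KO, whose sign was turned here so that a positive value means higher in KO. The deposited p-values came with an adjusted p-value, which equalled a Benjamini-Hochberg adjustment over all listed genes. Every count column was matched to a sample. Il25 and several ILC2 genes (Rora, Il1rl1, Klrg1, Il5, Arg1) were not analysed here, nor were mitochondrially encoded transcripts.

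The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10), which kept 9016 and removed 1897, and libraries were scaled by TMM, with factors from 0.949 to 1.058. A quasi-likelihood model with the group as the only term was fitted to all 8 libraries, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Libraries held 1915365 to 3250718 UMIs. The common biological coefficient of variation was 0.128. CPM values use the TMM-scaled library sizes. Genes were matched to GENCODE M21 by symbol, and 10694 had a single position.

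The test was checked on simulated counts for the 9016 tested genes with the real means, library sizes and fitted dispersions. Of changes of 1.5-fold, 42.8% were recovered, and of changes of 2-fold, 87%, while 7.4% of calls were false. These were 214 and 435 changes over 5 simulations, more per simulation than the 19 genes called in the data. More calls loosen a Benjamini-Hochberg threshold, so the shares can overstate what the real test recovers. A list raised by 1.4-fold was called in 20 of 20 simulations, and 5% of 420 tests of other lists lay at p under 0.05. Genes were drawn independently in these simulations, so members of a list did not move together. The 5% therefore says little about measured lists whose members are correlated, such as the heat shock list with an estimated correlation of 0.362.

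The gene lists, 22 of programs and 13 of other cell types, were fixed before the data were examined. The 25 with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 25 lists, and again with the correlation estimated per list. The 10 lists with fewer tested members (mitochondrially encoded transcripts, B cells, macrophages and monocytes, neutrophils, dendritic cells, tuft cells, fibroblasts and mural cells, endothelium, red cells, and mast cells, basophils and eosinophils) entered no camera test. The summed CPM of each of the 13 lists of other cell types was compared on the log2 scale with a pseudocount of 1 CPM by a two-sided exact permutation test over the 70 assignments, whose smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over the 13 lists.

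The genes named in the text follow a rule set before the data were examined: Il25, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, 15 key ILC2 genes, and for each list described up to 4 measured members with the lowest p, called members first. Junb, Klf6, Nfe2, Sstr2 and Gapdh are named outside the rule, after their values were seen, and 2 genes that the rule takes are not reported here and were not replaced.

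Alternatives covered the normalization (median of ratios, upper quartile, library size alone), the filter, the test (DESeq2 1.42.0, limma-voom with and without sample quality weights, a robust edgeR fit), a block for the replicate number, log2 total count as a covariate, other thresholds, and leaving out each library in turn. Covariates built from the heat shock list and from the thymocyte and T cell list, and the total count covariate for the lists, were added after seeing the data, as were the exact permutation tests of the mean log2 level of single lists.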

Results

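Group 2 innate lymphoid cells (ILC2), tissue-resident lymphocytes that make type 2 cytokines, were sorted from the enzymatically dissociated thymus of young male mice that had received no treatment. RNA of these cells was profiled in 8 libraries, 4 from mice lacking Il25 (Il25 KO) and 4 from age-matched wild-type (WT) mice. IL-25 is a cytokine released by tuft cells, a type of chemosensory epithelial cell, and it signals to ILC2 through a receptor made of IL17RB and IL17RA. The comparison asks which transcripts of the sorted thymic ILC2 samples differ when IL-25 is missing. The libraries counted the 3′ ends of polyadenylated transcripts with unique molecular identifiers (UMIs). The KO libraries (replicates 1 to 4) held 2613221, 1915365, 2932999 and 2526982 UMIs and the WT libraries 2398817, 2589564, 2852445 and 3250718. Across genes, log2 values of the 28 pairs of libraries correlated at Pearson's r of 0.962 to 0.978, and genes are not independent replicates. No pair agreed within sampling noise, so all 8 libraries were counted separately. The first principal component, with 22.6% of the variance, placed all 4 KO libraries below all 4 WT libraries (exact permutation p = 0.0286, two-sided, the smallest possible). The labels call the samples replicates without saying that each came from a separate animal, so the p-values measure the spread between these samples.

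Il25, the targeted gene, was not analysed here, so its transcript gave no check of the genotype labels. None of the 6 key ILC2 genes tested passed the threshold of an adjusted p under 0.05. Gata3, the transcription factor that specifies ILC2, stood at 70.9 ± 13.3 CPM (UMI counts scaled to a fixed library total) in KO and 60.6 ± 7.85 CPM in WT (SD, n = 4 each), a log2 fold change of 0.22 ± 0.14 (SE) with an edgeR adjusted p of 0.586. Il17rb, which encodes the IL-25 receptor chain, stood at 178 ± 9.95 CPM in KO and 154 ± 6.4 CPM in WT, with a log2 fold change of 0.20 ± 0.10 (SE) and an edgeR adjusted p of 0.46, and every KO library lay above every WT library. The log2 fold changes of Id2, Il7r and Il2ra were 0.13 ± 0.15, 0.22 ± 0.13 and 0.06 ± 0.15 (SE), with edgeR adjusted p of 0.778, 0.565 and 0.926. Areg, which encodes the repair factor amphiregulin, had a larger log2 fold change of 0.72 ± 0.22 (SE), also with no overlap between the groups, and an edgeR adjusted p of 0.218. Il4, Il13, Csf2 and Icos lay below the count filter. Il13 held 36 UMIs over the 4 KO libraries and 51 over the 4 WT libraries, and Il4 held 16 and 9, and neither gene was tested. Rora, Il1rl1, Klrg1, Il5 and Arg1 were not analysed here. Transcripts typical of thymocytes and T cells were present in all 8 libraries. Dntt, a gene of immature thymocytes, stood at 1835 to 2552 CPM and Cd3d at 120.5 to 317.9 CPM, where Gata3 stood at 49.0 to 82.4 CPM. Whether this RNA came from ILC2 or from other cells in the sorts was not tested, so a difference need not lie within ILC2.

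Of 9016 genes tested, 16 were higher and 3 lower in KO at an edgeR adjusted p under 0.05, and 7 of the 16 belong to the list of immediate early genes. Jun and Fos, which encode subunits of the AP-1 transcription factor, rose by log2 fold changes of 0.93 ± 0.14 and 0.84 ± 0.16 (SE). Jun reached 1230 ± 134 CPM in KO against 646 ± 146 CPM in WT, and Fos 488 ± 119 against 273 ± 48.0 CPM (SD, n = 4 each). Rhob, which encodes a small GTPase, had the lowest adjusted p and rose 1.92-fold, from 49.6 ± 6.09 to 95 ± 11.7 CPM, a log2 fold change of 0.94 ± 0.12 (SE) with an edgeR adjusted p of 0.00369. In each of the 19 genes the 4 KO and 4 WT libraries did not overlap. Over all tested genes this held for 471, or 5.22%, where chance gives 2.86%.

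The other called genes included regulators of signalling and surface molecules. Dusp1 and Dusp2, which encode phosphatases that act on MAP kinases, rose by 0.84 ± 0.14 and 0.75 ± 0.11 on the log2 scale (SE), and Egr1, a zinc finger transcription factor, rose by 0.76 ± 0.14. Cd69, an activation marker that holds lymphocytes in tissue, rose from 177 ± 28.3 to 292 ± 24.3 CPM. Klf2, a transcription factor that promotes egress from tissue, rose from 379 ± 104 to 677 ± 111 CPM, and Rgs1, which dampens chemokine receptor signalling, from 30.8 ± 6.0 to 54.9 ± 7.64 CPM. Maff, which encodes a small bZIP factor, rose by 0.89 ± 0.18 on the log2 scale (SE), and the chemokine gene Ccl4 by 0.75 ± 0.13. Ifng, which encodes interferon gamma and is a marker of NK cells and ILC1, rose from 177 ± 15 to 280 ± 41.2 CPM (edgeR adjusted p = 0.0187). Junb, Klf6, Nfe2 and Sstr2 completed the rises, with log2 fold changes of 0.65 ± 0.13, 0.65 ± 0.13, 0.65 ± 0.11 and 0.63 ± 0.12 (SE), and these 4 genes were named after their values were seen.

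The genes that fell were Klf7, Tnfrsf18 and H2-Q2. Klf7, a Krüppel-like transcription factor, fell 2.09-fold, from 57.6 ± 9.12 CPM in WT to 27.9 ± 6.61 CPM in KO (edgeR adjusted p = 0.0099). Tnfrsf18, which encodes the costimulatory receptor GITR, fell 1.73-fold, from 137 ± 5.84 to 79.7 ± 17 CPM (edgeR adjusted p = 0.0134). H2-Q2, an MHC class I gene, fell 2.21-fold, from 35.8 ± 10.7 to 16.2 ± 3.06 CPM (edgeR adjusted p = 0.0187). H2-Q2 belongs to a family of near-identical genes, so its counts are uncertain where reads could be split between family members. In GENCODE M21 coordinates (GRCm38, the assembly of mm10), H2-Q2 lies on chromosome 17 from 35342242 to 35346762, Klf7 on chromosome 1 from 64029447 to 64122282, Tnfrsf18 on chromosome 4 from 156026164 to 156028895, Rhob on chromosome 12 from 8497661 to 8500009 and Jun on chromosome 4 from 95049034 to 95052222. Genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 977 genes lay at an unadjusted p under 0.05. The number of calls was 1 without WT replicate 2, 4 without WT replicate 4 and 39 without KO replicate 2, and by DESeq2 it was 45, of which 29 higher and 16 lower. With the mean of the heat shock list as a covariate, chosen after seeing the data, edgeR called 0 genes at adjusted p under 0.05 and 693 lay at an unadjusted p under 0.05, and with the thymocyte and T cell list mean, also chosen after seeing the data, it called 13 higher and 0 lower, with Klf7, Tnfrsf18 and H2-Q2 at log2 fold changes of -0.94, -0.77 and -0.81 (edgeR adjusted p of 0.0578, 0.0613 and 0.115).

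**Figure D1:**
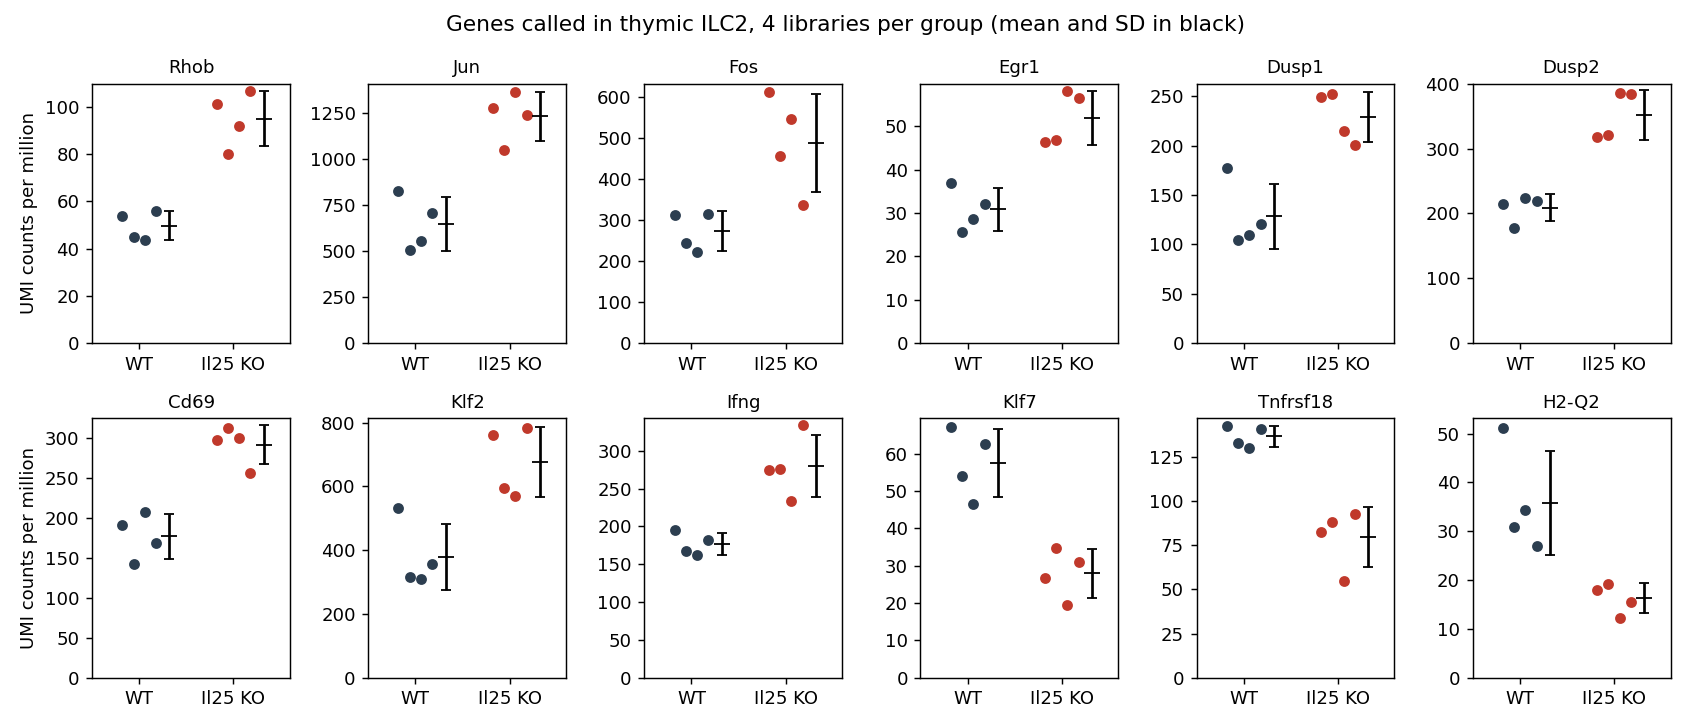
UMI counts in CPM of 12 of the 19 called genes in each of the 4 WT and 4 Il25 KO libraries (points), with the group mean and SD in black; each axis starts at 0. In each panel the points of the groups do not overlap, and Klf7, Tnfrsf18 and H2-Q2 are the 3 genes with lower values in KO.

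Gene lists fixed before the data were examined were tested with camera. Of 25 lists with at least 5 tested members, 12 were called with a preset correlation of 0.01, and with an estimated correlation only the list of immediate early genes was called. Of its 22 tested members, 7 rose, 0 fell and 15 did not pass, and 17 rose when adjusted over the list alone. The mean log2 fold change of the list was 0.51 and its camera adjusted p was 4.53e-28, or an adjusted p of 0.0166 with an estimated correlation. The mean log2 level of the list was higher in all 4 KO libraries than in any WT library (exact permutation p = 0.0286, two-sided, the smallest this design can give).

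The list of heat shock and dissociation stress genes moved in the same direction. None of its 11 tested members passed over all genes and 4 rose when adjusted over the list alone. Its mean log2 fold change was 0.28 and its camera adjusted p was 7.92e-06, which became an adjusted p of 0.212 with an estimated correlation. The mean log2 level of the list was 0.28 higher in KO (exact permutation p = 0.0571, two-sided). The groups overlapped, with WT replicate 4 at 10.343 above KO replicate 2 at 10.32. The chaperone genes Hspa1b and Hspa1a were among the abundant transcripts of both groups, at 9613 ± 1647 and 9072 ± 1687 CPM in KO and 6299 ± 1412 and 6115 ± 1440 CPM in WT (SD, n = 4). Their log2 fold changes were 0.61 ± 0.16 and 0.57 ± 0.16 (SE), with edgeR adjusted p of 0.153 and 0.196. Dnajb1 and Hspa8, a co-chaperone and a constitutive chaperone, had log2 fold changes of 0.35 ± 0.13 and 0.31 ± 0.12 (SE).

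Cytokine and growth factor lists were higher in KO, though no member of either passed over all genes. In the list of type 2 and other effector cytokines, 4 of 7 tested members rose when adjusted over the list alone, and the mean log2 fold change was 0.56 (camera adjusted p = 1.28e-05, and adjusted p = 0.0816 with an estimated correlation). Those 4 were Il10, Lif, Cxcl2 and Areg, with log2 fold changes of 0.94 ± 0.22, 0.85 ± 0.20, 1.21 ± 0.33 and 0.72 ± 0.22 (SE), and the type 2 cytokine genes Il4 and Il13 were not among the tested members. Il10 stood at 25.2 ± 5.35 CPM in KO and 13.1 ± 4.01 CPM in WT (edgeR adjusted p = 0.0953). In the list of growth and repair factors, 3 of 10 tested members rose when adjusted over the list alone, and the mean log2 fold change was 0.39 (camera adjusted p = 4.61e-05, and adjusted p = 0.105 with an estimated correlation). It shares Lif and Areg with the cytokine list, and Tgfb1 and Tnfsf10 had log2 fold changes of 0.48 ± 0.15 and 0.61 ± 0.29 (SE).

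NF-kB target genes and migration genes were also called higher. Among 19 NF-kB target genes 1 rose, Ccl4, and 3 rose when adjusted over the list alone. The mean log2 fold change was 0.17 (camera adjusted p = 0.000955, and adjusted p = 0.212 with an estimated correlation). Ccl3 and Nfkbid had log2 fold changes of 1.13 ± 0.29 and 0.36 ± 0.12 (SE), while Relb had -0.84 ± 0.33. Of 16 migration and tissue residency genes, Cd69, Rgs1 and Klf2 rose, 0 fell and 13 did not pass, and 4 rose when adjusted over the list alone. The mean log2 fold change was 0.08 (camera adjusted p = 0.00151, and adjusted p = 0.0816 with an estimated correlation). Cxcr4, a chemokine receptor gene, had a log2 fold change of 0.45 ± 0.16 (SE), and the members went both ways, with 10 above and 6 below 0. With the heat shock list mean as a covariate, the mean log2 fold changes of the cytokine, growth factor, NF-kB and migration lists became 0.297, 0.257, 0.021 and -0.022, with camera adjusted p of 0.153, 0.104, 0.646 and 0.153. With it the mean of the immediate early list was 0.383, with a camera adjusted p of 2.11e-09, or an adjusted p of 0.232 with an estimated correlation.

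Of the lists for proliferation and biosynthesis, G2 and M phase was higher, and oxidative phosphorylation and ribosomal proteins were lower in KO, each with small shifts and 0 members called. The mean log2 fold change of 24 G2 and M phase genes was 0.14, with 23 members above 0 (camera adjusted p = 0.00151, and adjusted p = 0.395 with an estimated correlation). Aurkb, Nusap1, Kif20a and Kif23, which act in mitosis, had log2 fold changes of 0.27 ± 0.11, 0.34 ± 0.14, 0.32 ± 0.13 and 0.24 ± 0.12 (SE). The mean over 37 oxidative phosphorylation genes was -0.14, with 30 members below 0 (camera adjusted p = 0.000458, and adjusted p = 0.354 with an estimated correlation). Cox8a, Atp5j, Uqcrb and Cox7b had log2 fold changes of -0.48 ± 0.14, -0.43 ± 0.13, -0.79 ± 0.24 and -0.33 ± 0.15 (SE). The mean over 51 ribosomal protein genes was -0.10 (camera adjusted p = 0.00583, and adjusted p = 0.495 with an estimated correlation), and its members went both ways, with Rps9 at -0.62 ± 0.20, Rpl35 at -0.46 ± 0.16, Rps16 at -0.39 ± 0.13 and Rpl38 at 0.47 ± 0.14 (SE). Near-identical pseudogenes can take reads of ribosomal protein genes. The G2 and M phase call ended without KO replicate 3 (mean 0.083, adjusted p = 0.0545) and without WT replicate 1 (mean 0.084, adjusted p = 0.11), the ribosomal call without KO replicate 1 (mean -0.047, adjusted p = 0.211), and the oxidative phosphorylation call with the heat shock covariate (mean -0.06, adjusted p = 0.404).

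The lists of costimulatory and inhibitory receptors, of thymocytes and T cells and of ILC3 were lower in KO. Among 10 receptor genes 1 fell, Tnfrsf18, and 3 fell when adjusted over the list alone. The mean log2 fold change was -0.18 (camera adjusted p = 0.0356, and adjusted p = 0.233 with an estimated correlation). The inhibitory receptor gene Pdcd1 had a log2 fold change of -0.55 ± 0.14 (SE), and the costimulatory receptor genes Cd28 and Tnfrsf4 had -0.61 ± 0.20 and -0.76 ± 0.38. None of 17 thymocyte and T cell genes passed over all genes and 6 fell when adjusted over the list alone, with a mean log2 fold change of -0.40 (camera adjusted p = 0.000398, and adjusted p = 0.354 with an estimated correlation). Cd3d, a chain of the CD3 complex, stood at 152 ± 35.5 CPM in KO and 252 ± 45.9 CPM in WT (log2 fold change -0.73 ± 0.15, SE, edgeR adjusted p = 0.0521). Ptcra and Cd8b1 had log2 fold changes of -0.66 ± 0.15 and -1.64 ± 0.45 (SE). The mean log2 level of the list was lower in all 4 KO libraries than in any WT library (difference -0.309, exact permutation p = 0.0286, two-sided), while its summed CPM was 5386 ± 251 in KO and 5259 ± 646 in WT (SD, n = 4). Of the 17 members 12 lay below and 5 above 0, so the list did not move as 1. Dntt, which holds a large part of the summed CPM, stood at 2179 to 2552 CPM in KO and 1835 to 2118 CPM in WT. Its log2 fold change was 0.25 ± 0.11 (SE, edgeR adjusted p = 0.41), with no overlap between the groups. None of 9 ILC3 genes passed over all genes and 3 fell when adjusted over the list alone, with a mean log2 fold change of -0.41 (camera adjusted p = 0.0166, and adjusted p = 0.233 with an estimated correlation). Nrp1 and Ahr had log2 fold changes of -1.14 ± 0.30 and -0.56 ± 0.21 (SE), and Tmem176b 0.19 ± 0.11.

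WT replicate 1 stood apart in some T cell and MHC class II genes. It held 357 CPM of Cd8b1, a T cell coreceptor gene, where the other WT libraries held 55.7 to 65.2 CPM and the KO libraries 33.7 to 48.1 CPM, and without it the log2 fold change of Cd8b1 was -0.50 ± 0.14 (SE). It also held 110 CPM of the MHC class II gene H2-Aa, where the other WT libraries held 11.9 to 18.4 CPM. The list of MHC class II presentation was not called, with a mean log2 fold change of -0.41 over 8 tested members (camera adjusted p = 0.33). H2-Aa, H2-Ab1 and H2-Eb1 had log2 fold changes of -1.23 ± 0.51, -0.68 ± 0.27 and -1.32 ± 0.71 (SE), and H2-Ob 0.60 ± 0.30. Without WT replicate 1 the log2 fold changes of H2-Aa, H2-Ab1 and H2-Eb1 were 0.03, -0.16 and 0.82. Without it the means of the thymocyte and T cell, ILC3 and receptor lists were -0.125, -0.285 and -0.146, with camera adjusted p of 0.0861, 0.0915 and 0.116, while edgeR called 26 genes, 21 higher and 5 lower. The receptor call also ended without KO replicate 2 (mean -0.133, adjusted p = 0.176), KO replicate 4 (mean -0.204, adjusted p = 0.0739) or WT replicate 4 (mean -0.161, adjusted p = 0.085) and with log2 total count as a covariate (mean -0.154, adjusted p = 0.121). The ILC3 call also ended without KO replicate 3 (mean -0.38, adjusted p = 0.0792) and with the heat shock covariate (mean -0.411, adjusted p = 0.0926).

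**Figure D2:**
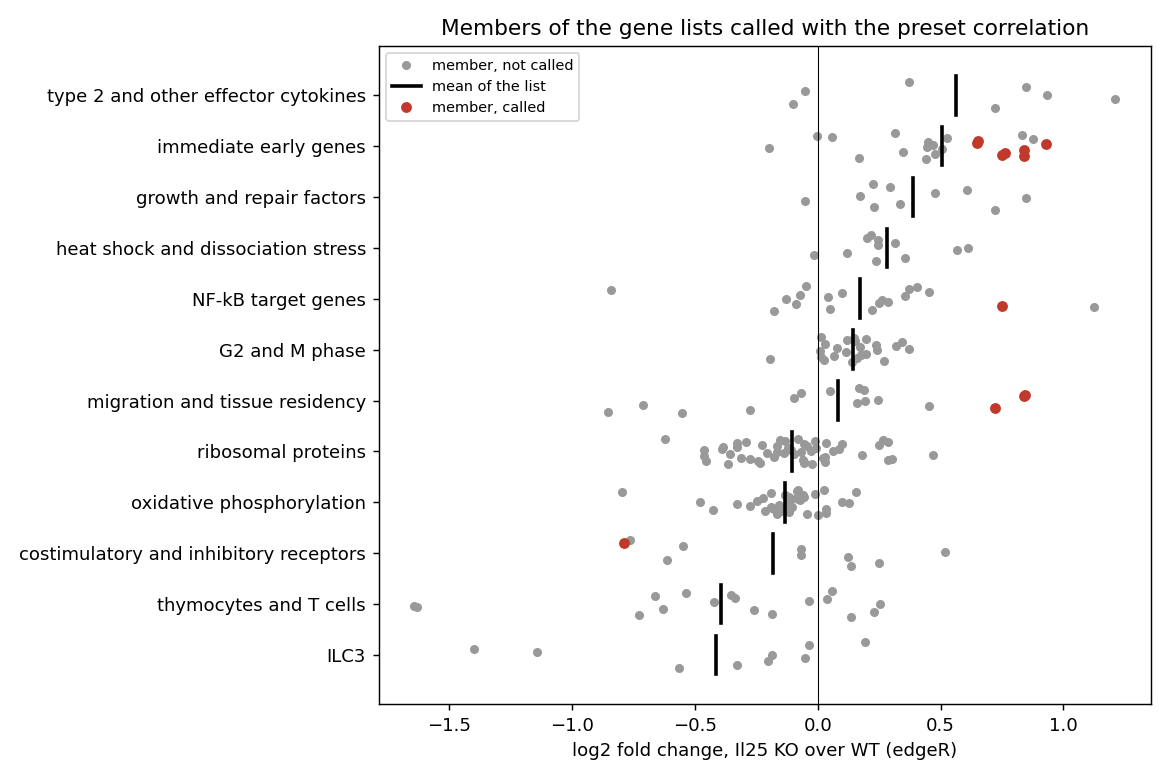
Log2 fold changes (Il25 KO over WT, edgeR) of the tested members of the 12 gene lists called by camera with the preset correlation; grey points are members that were not called, red points called members and black bars the mean of each list. The immediate early list holds 7 called members, and the thymocyte and ILC3 lists hold 0.

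The ILC2 identity list was not called. Of its 17 tested members 0 rose and 0 fell over all genes, and 1 rose and 2 fell when adjusted over the list alone. Its mean log2 fold change was -0.02, whereas its median was 0.14 and camera's direction was up (camera adjusted p = 0.391). Cd2, an adhesion receptor gene, had a log2 fold change of -1.87 ± 0.42 and Ly6a of -0.63 ± 0.18, while the transcription factor genes Gfi1 and Bcl11b had 0.48 ± 0.14 and 0.41 ± 0.17 (SE). Cd2 stood at 52.9 CPM in WT replicate 1 and at 13.3 to 14.3 CPM in the other WT libraries, and without that library its log2 fold change was -1.15 ± 0.25 (SE, edgeR adjusted p = 0.0653). Among 12 genes of IL-25 and alarmin receptor signalling none passed either adjustment, and the mean log2 fold change was 0.03 (camera adjusted p = 0.446). The receptor chain gene Il17ra and the adaptor gene Traf3ip2 had log2 fold changes of 0.10 ± 0.11 and 0.24 ± 0.18 (SE).

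Summed markers of 13 other cell types were compared by an exact permutation test, in which a single list that separated the groups fully would have an adjusted p of 0.371, so the adjusted values say little about whether the groups differ. The smallest unadjusted exact permutation p was 0.257, for dendritic cells. The NK cell and ILC1 total was 1108 ± 77.0 summed CPM in KO and 1092 ± 86.8 in WT (SD, n = 4). In that list Ifng rose, and Gzma, which encodes a granzyme, stood at 505 ± 82.9 CPM in KO and 626 ± 75.7 CPM in WT. Nkg7 and Ccl5 had log2 fold changes of 0.19 ± 0.12 and -0.40 ± 0.30 (SE), and the list had a camera adjusted p of 0.19. Without WT replicate 1 the log2 fold change of Ccl5 was 0.08. The macrophage and monocyte total was 71.0 ± 7.46 summed CPM in KO and 87.6 ± 71.8 in WT, where WT replicate 1 held 195 and the other WT libraries 44.1 to 59.5. The KO libraries held 62.5 to 80.2, and without WT replicate 1 the log2 difference of this total turned to 0.45.

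**Figure D3:**
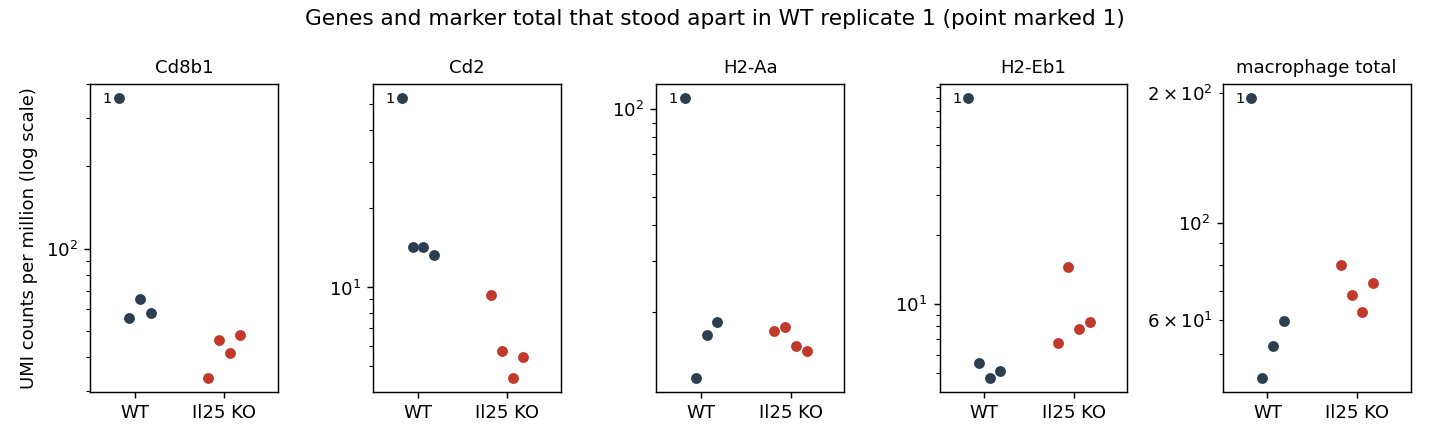
UMI counts in CPM, on log axes, of 4 genes and summed CPM of the macrophage and monocyte markers in each WT and Il25 KO library (points). The point marked 1 is WT replicate 1, which lies above all 7 other libraries in every panel.

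The authors' deposited table held their own comparison of the same libraries. Among its genes, 36 had an adjusted p under 0.05, 24 higher and 12 lower in KO, and 3 of the 36 had an absolute log2 fold change of at least 1. All 19 edgeR calls were among the 36 genes of the authors' deposited table, each in the same direction. The 17 genes called only in the authors' deposited table included Cd3d, at an adjusted p of 0.00491 there, and Hspa1b, at 0.0274.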

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

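The tests of a heat shock difference as the whole cause, of thymocyte carry-over with and without WT replicate 1, of WT replicate 1 alone and of exchange within the H2-Q family as the whole cause were chosen only after the results were seen, as was the heat shock covariate for single genes.

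Immediate early genes stood higher in KO, with a mean log2 fold change of 0.506. Lower depth of the KO libraries is argued against by the size of the change, of which 103% (SE 9.3) was kept with log2 total count as a covariate (camera adjusted p = 1.46e-26, or 0.0513 with an estimated correlation). With the heat shock list mean as a covariate 75.7% (SE 13.4) was kept, a mean of 0.383 ± 0.094 (jackknife SE), with a camera adjusted p of 2.11e-09, or 0.232 with an estimated correlation. A heat shock difference as part or whole of the cause could therefore not be told apart from its absence, and the covariate is itself measured with error. Handling that acts on immediate early genes without heat shock genes was not tested, so sorting or dissociation differences and the genotype may both still account for the pattern.

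The same covariate ended all 19 gene calls. The median absolute log2 fold change of the 19 genes went from 0.789 to 0.606 and the median SE from 0.134 to 0.199, and the share of each in the lost calls was not tested. All 19 kept their direction and 17 lay at an unadjusted edgeR p under 0.05, and the lowest edgeR adjusted p was 0.257.

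Chance is argued against but not excluded for the number of genes, and it stays open for the number of lists. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes, the real one with 19, and the highest other split gave 7. A share of 1 in 35 is the smallest this test can give. The calls fell to 1 without WT replicate 2 and to 4 without WT replicate 4, where fewer samples also lower the power. As many lists came from 3 of the 35 splits, with 12 in the real split and 13 in the highest other. The other splits among these 3 kept KO replicates 1, 3 and 4 together and so held much of the real contrast. Splits with 2 KO libraries on each side gave at most 10 lists. The share of 3 in 35 is therefore no clean estimate of what chance gives. With an estimated correlation the real split called 1 list and the highest other 0.

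WT replicate 1 lay far from the other WT libraries in markers of several cell types. It held 52.9 CPM of Cd2 (others 13.3 to 14.3), 357 of Cd8b1 (55.7 to 65.2), 51.6 of Ccl5 (17.8 to 20.2), 155 of H2-Ab1 (47.6 to 64.5), 110 of H2-Aa (11.9 to 18.4) and 80.4 of H2-Eb1 (4.76 to 5.53). Its marker totals in summed CPM were 6220 for thymocytes and T cells (4840 to 5030), 195 for macrophages and monocytes (44.1 to 59.5), 2.57 for red cells (0 in the others) and, on the low side, 962 for NK cells and ILC1 (1120 to 1140). The red cell total is 1 gene at 0 in every other library. Every listed gene had at least 6 counts in some library, so this gene was listed only through WT replicate 1. Its standing apart was thus fixed in advance and is no evidence of red cell RNA.

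The thymocyte and T cell list was lower in KO by a mean log2 fold change of -0.395. Without WT replicate 1 it was -0.125 ± 0.025 (jackknife SE) with a camera adjusted p of 0.0861, so RNA of other cells in that library may explain much of the shift, while a remainder in the same direction stays open, with Cd3d at -0.595 ± 0.146 (SE, edgeR adjusted p = 0.0882). The median of 7 immature thymocyte genes was -0.353 with all libraries, above Cd3d at -0.726 by 0.373 (combined SE 0.411), and 0.158 without WT replicate 1, with 4 of the 7 genes higher in KO. That is above Cd3d by 0.752 (combined SE 0.222) but above the mean of the list by only 0.282 (combined SE 0.17). The 7 genes did not move together without that library. Ptcra at -0.528 ± 0.146 and Cd8b1 at -0.503 ± 0.14 lay near Cd3d, while Dntt lay at 0.299 ± 0.126 (SE). Their median therefore cannot decide the source of the Cd3d difference. For Cd3d and for the list, fewer thymocytes carried into the KO sorts could not be told apart from a change within ILC2, and carry-over of mature T cells was not tested.

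H2-Q2 was lower in KO. Exchange of reads among the 5 H2-Q genes analysed here as the whole cause is argued against. Their summed CPM, the family total, differed by -30.2 CPM (SE 7.9). The members other than H2-Q2 stood at 49.4 CPM in KO and 60.1 CPM in WT (difference -10.7, SE 6.8), where exchange needs them higher in KO. Exchange with H2-Q genes outside these 5 was not tested. The family total showed 47.9% (SE 14.9) of the H2-Q2 log2 change, a share that would be 28.8% with the other members unchanged and so is no evidence of exchange, and a small exchange within the error of the other members stays open. Of 134 genes within 5 Mb of H2-Q2 on chromosome 17, 9% lay at an unadjusted edgeR p under 0.05 against 10.7% of the rest. The exact upper 95% limit of 15.1% lies below 21.4%, or 2 times the share of the rest, which argues against an excess of that size. A strain difference in that block that changes few genes stays open. A variant in H2-Q2 alone, reads lost to other MHC class I genes and the genotype were not tested.

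The count that follows includes the red cell total of WT replicate 1, which the listing of its gene fixed. Of 171 groups of 4 values checked for 1 value far from the other 3, 16 stood out, where about 5% would by chance. Besides those of WT replicate 1, they were WT replicate 4 in Rgs1 (21.9 CPM, others 32.8 to 34.6), WT replicate 2 in Nrp1 (13.4, others 7.62 to 7.81), Dnajb1 (773, others 1030 to 1070) and Ahr (24.9, others 16.2 to 17.7), WT replicate 3 in Rps9 (2850, others 3930 to 3970) and KO replicate 3 in Kif23 (145, others 110 to 112).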

How the results depend on the processing

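The covariates built from the heat shock and thymocyte lists, and the total count covariate for lists, were chosen only after the results were seen. Over 23 alternatives the 19 called genes gave 437 values, of which 0 turned direction and 106 lost the call, and Rhob was the only gene called without each library. Of 1205 values of 53 named genes that were not called, 12 turned direction and 31 passed the threshold. Median-of-ratios, upper-quartile and library size scaling kept all 19 calls, with 81% to 84.2% of calls higher in KO.

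Genes higher, lower and in all were 29, 16 and 45 by DESeq2, 29, 14 and 43 by limma-voom with sample quality weights, 25, 15 and 40 with log2 total count as a covariate, 26, 16 and 42 at adjusted p under 0.1, and 0, 0 and 0 with the heat shock covariate. The robust edgeR fit called 8 lower, the thymocyte covariate 13 higher and 0 lower (10 of the 19 calls were kept), and a required absolute log2 fold change of 1 left 0 higher and 2 in all. Leaving out 1 library gave 1 to 27 higher, 0 to 12 lower and 1 to 39 in all. The authors' table shared 39 calls at adjusted p under 0.1. Lists called were 1 with an estimated correlation, 3 by fry and 6 with the heat shock covariate. The cause of these differences was not tested. Fewer samples lower the power, yet the 39 calls came from the fit without KO replicate 2.

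A block for equal replicate numbers in the sample titles called 32 higher, 28 lower and 60 in all, 12 lists and 0 marker totals. The file headers number the KO and WT columns differently, and no source used here says that equal numbers share a litter or day. Not every sample correlated best with its own number (own-number correlations 0.138, -0.006, 0 and 0.089, and KO replicate 2 had 0.242 with another number), a hint from the data and not from the design.

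Results that turned direction follow, and the cause was not tested. With quality weights H2-Eb1 was 0.2. With the heat shock covariate Id2 was -0.138. With the thymocyte covariate Ccl5 was 0.315, H2-Aa 0.518, H2-Ab1 0.105, H2-Eb1 1.529 and Il2ra -0.162. Camera's direction turned for apoptosis regulators (means -0.018 without a filter, -0.024 with the replicate block, -0.016 with the total count covariate) and for glycolysis (0.018 with the total count covariate). List means turned to 0.01 for ILC2 identity and 0 for apoptosis regulators on library size alone, -0.041 for IL-25 and alarmin signalling and -0.014 for STAT5 targets without a filter, and -0.022 for migration and -0.053 for NK cells and ILC1 with the heat shock covariate. Marker totals as the mean of log2 CPM were -0.309 for thymocytes, -0.123 for B cells, -0.2 for fibroblasts, -0.022 for endothelium and 0.315 for mast cells, and on plain library sizes 0.002 for macrophages and 0.003 for neutrophils.

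Ranges over the fits without 1 library were -0.071 to 0.226 for Il2ra (below 0 without KO replicate 3 and WT replicate 1), and, turning without WT replicate 1, -0.565 to 0.082 for Ccl5, -1.53 to 0.03 for H2-Aa, -1.685 to 0.82 for H2-Eb1 and -0.57 to 0.223 for the MHC class II list. The mean of ILC2 identity ranged from -0.069 to 0.024 (above 0 without KO replicate 4 and WT replicate 1). Camera's direction turned within -0.052 to -0.003 for apoptosis regulators, -0.28 to -0.062 for glycolysis and -0.16 to -0.025 for interferon response. Marker totals ranged from -0.005 to 0.037 for B cells, -0.134 to 0.013 for ILC3, -0.038 to 0.065 for NK cells and ILC1, -0.069 to 0.089 for endothelium, -0.171 to 0.201 for fibroblasts, -0.257 to 0.45 for macrophages, -0.236 to 0.088 for mast cells, -0.255 to 0.181 for neutrophils and -0.009 to 0.163 for thymic epithelium. In the simulations 42.8% of 1.5-fold changes were recovered, a share that can overstate the real test, where fewer genes were called.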

Other observations

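The test of a strain difference around Il25 was set before its result was seen. The lists for proliferation in S phase, interferon response, STAT5 targets, the unfolded protein response, cholesterol synthesis, glycolysis, neuropeptide and lipid mediator receptors, apoptosis and thymic epithelium were not called, with mean log2 fold changes of 0.09, -0.12, 0.06, 0.07, 0.06, -0.11, 0.06, -0.03 and 0.15 and camera adjusted p of 0.0531, 0.358, 0.33, 0.267, 0.33, 0.734, 0.439, 0.926 and 0.358. In these lists Irf1, an interferon-induced transcription factor gene, had a log2 fold change of 0.51 ± 0.12 (SE, edgeR adjusted p = 0.0904), and the glycolytic gene Eno1 had -0.62 ± 0.17 (SE, edgeR adjusted p = 0.185). Of the 24 interferon response genes 10 lay above and 14 below 0, with Oasl2 at -0.86 ± 0.27 and Ifi44 at -0.99 ± 0.33 (SE). The S phase list was called without KO replicate 2 (camera adjusted p = 0.0126), WT replicate 3 (0.0271) and WT replicate 4 (0.0203), the NK cell and ILC1 list without KO replicate 3 (0.0495) and the MHC class II list without WT replicate 3 (0.0333). S phase was also called on library size alone, without a filter and with log2 total count as a covariate. MHC class II was also called with the heat shock covariate.

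Genes near Il25 could carry differences of the strain in which the locus was targeted. Of 117 genes within 10 Mb of Il25 on chromosome 14, 12 or 10.3% lay at an unadjusted edgeR p under 0.05, against 10.7% of the rest (Fisher exact p = 1), and the exact upper 95% limit of 17.2% lies below 21.3%, or 2 times the share of the rest, which argues against an excess of that size.

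Gapdh, a gene with many processed pseudogenes that is named outside the rule, ranged from 15.1 to 621 CPM in KO and from 21.5 to 1167 CPM in WT.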
